A study of Mus musculus with 9 samples.

How the data were processed

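Bulk RNA sequencing was used to measure gene expression in 9 libraries from hearts of wild-type mice. Per the labels, 3 libraries are of sham operation, 3 of hearts 1 day and 3 of hearts 7 days after surgery that caused a myocardial infarction. The labels do not give the day on which the sham hearts were collected, so the same 3 sham libraries served as the control for both times. The series also describes hearts of mice without Hdc, the gene of the histamine-forming enzyme. Those hearts were not analysed here.

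Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. Per the submitters' processing notes, the tools were FastQC 0.11.9, HISAT2 2.1.0 and HTSeq 0.11.2, and the genome build was GRCm39. The annotation release, and whether counting used strand, are not given in the sources used here. The deposited values are FPKM (sequenced fragments, normalised to transcript length and library size) made by the authors. The file held 55361 transcript entries, so a gene had as many values as it had transcripts in the file. Of the positive values, 11.8% were under 1e-06, and 1 whole read on a transcript of 100 kb among 1e+09 reads gives 1e-05, so reads had been counted in fractions, as when they are divided among transcripts. The tool that did this is not given in the sources used here. Because of these fractions, the number of reads behind a value could not be recovered and the depth of each library is unknown. The FPKM of all genes summed to between 521643 and 792632 per library, so libraries had not been rescaled to a common total.

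The design fixed beforehand assumed 1 value per gene. The FPKM of a gene was therefore taken as the sum over its transcripts, which gave 25468 genes. A gene was tested if its mean over the 9 libraries was 1 FPKM or more, which kept 13514 genes. Of these, 12444 were protein coding by the gene types in the file. The GENCODE M21 annotation of GRCm38 is of another build than the authors used. It served only for gene names and the question of which genes overlap, and no coordinates are given. Of the 223 genes named by the rule below, 67 have an exon that overlaps an exon of another gene, 21 of them on the same strand. Without counting by strand, reads from overlapping genes cannot be told apart.

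Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean level and 1 mean per group. The 9 libraries shared 1 estimate of the spread. Tests were two-sided and p-values were adjusted with the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with a low level. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so none is reported. Levels are means ± SD in FPKM over n = 3 libraries, and the error of a fold change is its standard error (SE) from limma. Fold changes written with ± carry the SE. The labels do not say that the libraries of a group came from separate animals. P-values therefore measure the spread between these libraries, which may be technical in part.

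Before the data were examined, the tests, their alternatives, 41 gene lists and a rule for the genes to be named had been fixed. The lists covered the endoplasmic reticulum (ER), mitochondrial dynamics and metabolism, markers of cell types of the heart and its surroundings, and injury responses. Of their 743 entries, 738 matched a gene in the file. The rule named, for each comparison, the 8 largest rises and the 8 largest falls among called genes with no overlap of the groups and a mean of 5 FPKM or more in the higher group. Predicted and clone names were excluded there. It also named the genes the series concerns, and up to 4 called members of each list. Lists were tested with camera, which compares the members with all other genes, at a preset correlation between genes of 0.01. At least 3 tested members were required. The B cell list had fewer, so 40 lists were tested. Camera was run again with a correlation estimated from the residuals and on ranks, and fry was run as a test of the list by itself.

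The alternatives were a pseudocount of 0.1, no filter or a minimum mean of 5 FPKM, quantile and median-ratio normalisation, rescaling to a common total (TPM), leaving out mitochondrially encoded genes before rescaling, limma without the trend or with robust estimation, a fit of only the 2 groups compared, replicate numbers as a block, array weights, and leaving out each library in turn. Chosen after seeing the data were the most expressed transcript in place of the sum, a score of atrial genes as a covariate, and leaving out 2 pairs of libraries. The medians of lists under each scaling were also looked at after the results were seen. The procedure was tested on simulated data for the 13514 genes with the spread of these libraries and 200 changed genes per draw, in 10 draws. For day 1 against sham, it recovered 33.9%, 77.2% and 93.0% of genes changed by a log2 of 0.5, 1 and 2, and 5.98% of its calls were false. For day 7 against sham, recovery was 31.2%, 76.1% and 92.4%, with 4.43% false calls. For day 7 against day 1, it was 35.1%, 75.8% and 92.1%, with 4.93% false calls. A simulated list of 20 members shifted by a log2 of 0.5 was called in 10 of 10 draws in each comparison, and 0 of 390 unshifted lists were called. Simulated genes varied independently, unlike the genes of a tissue. Each draw changed fewer genes than were called here in any comparison, and the adjustment depends on the share of changed genes. The simulated rates therefore need not hold for the real comparisons.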

Results

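Gene expression was measured by bulk RNA sequencing in 9 libraries from hearts of wild-type mice. They formed 3 groups of 3 libraries: sham operation, 1 day after infarction and 7 days after infarction. FPKM summed to 792632, 791758 and 768943 in the sham libraries, to 619145, 597380 and 729940 at day 1 and to 521643, 644943 and 679204 at day 7. The number of reads behind these values is unknown. Mitochondrially encoded genes took 39.6%, 38.8% and 38.5% of the FPKM in sham, 35.7%, 34.2% and 39.8% at day 1 and 24.4%, 36% and 38% at day 7.

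Markers of neighbouring tissues differed within groups. The atrial light chain gene Myl7 was at 619, 13.2 and 30.1 FPKM in sham, at 2403, 928 and 35 at day 1 and at 497, 127 and 227 at day 7. Scgb1a1, a secretory protein of airway epithelium, was at 172 FPKM in sham replicate 1 and 780.2 in day 1 replicate 2, against 14.3 or less in the other libraries. The fat cell gene Cfd was at 336 FPKM in sham replicate 1 and at 60.5 or less elsewhere. In day 7 replicate 2, the T cell genes Cd3e and Cd8a were at 15.5 and 15.9 FPKM, against 3.67 and 2.95 or less elsewhere. The skeletal muscle gene Actn3 was at 11 FPKM there and at 0.291 or less in the others.

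The title of the series concerns AI662270, a noncoding RNA gene, and GRP94, the chaperone of the endoplasmic reticulum (ER) encoded by Hsp90b1, in acute infarction. It relates them to the unfolded protein response and mitochondrial dynamics. The comparison of day 1 with sham addresses how these genes differed early after infarction. AI662270 rose from 3.21 ± 1.07 FPKM in sham to 11.7 ± 2.28 at day 1 (log2 fold change 1.62, SE 0.27, adjusted p = 0.00546). Hsp90b1 rose from 231 ± 12 to 385 ± 22.3 FPKM (log2 fold change 0.73, SE 0.10, adjusted p = 0.00292). Hspa5, the main Hsp70 chaperone of the ER, rose from 240.2 ± 24.8 to 359 ± 43.2 FPKM (log2 fold change 0.57, SE 0.12, adjusted p = 0.0122). Hdc was at 2.12 ± 0.174 FPKM in sham and 3.84 ± 2.07 at day 1, which did not pass the test (adjusted p = 0.183). AI662270 overlaps another gene model on its strand and Hsp90b1 overlaps others on both strands, so part of their reads may belong to these.

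Of the ER chaperones and folding enzymes, 18 of 22 rose and 0 fell, and adjusted over the list alone 20 rose (camera adjusted p = 8.72e-13, adjusted p = 0.392 with an estimated correlation). The list included Sdf2l1 (1.71 ± 0.12), Pdia4 (1.35 ± 0.09), Creld2 (1.33 ± 0.11) and Pdia6 (1.16 ± 0.11). Of the genes of ER-associated degradation, which clears misfolded proteins, 6 of 16 rose, the same number adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.392 with an estimated correlation). Examples were Edem1 (0.91 ± 0.15) and Edem2 (0.56 ± 0.10). The ER stress sensors and stress-induced transcription factors had 5 and 3 of 21 members higher and lower, against 6 and 4 adjusted over the list alone, and were not called (camera adjusted p = 0.718). Their median log2 fold change was 0.09, their mean -0.02, and camera's direction was up. Ddit3, which encodes the stress transcription factor CHOP, fell from 43.8 ± 21.6 to 14.2 ± 0.856 FPKM (log2 fold change -1.46, SE 0.27, adjusted p = 0.00793).

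Some genes of mitochondrial dynamics were lower at day 1. The fusion gene Mfn1 fell from 123 ± 9.02 to 72.6 ± 7.16 FPKM (log2 fold change -0.76, SE 0.21, adjusted p = 0.0295) and Mfn2 from 158 ± 18.9 to 90.9 ± 7.63 FPKM (log2 fold change -0.79, SE 0.17, adjusted p = 0.0123). The fission genes Mff and Dnm1l fell too (-0.55 ± 0.12 and -0.36 ± 0.11, adjusted p = 0.0146 and 0.0463). Fis1 and Opa1 did not pass the test (adjusted p = 0.0547 and 0.178). In the fission list 5 of 9 fell, and 7 adjusted over the list alone (camera adjusted p = 0.00269, adjusted p = 0.392 with an estimated correlation). For fusion and inner membrane shape 10 of 15 fell, and 13 adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.486 with an estimated correlation). For mitophagy, the removal of mitochondria, 6 of 14 fell, such as Pink1 (-0.59 ± 0.17) and Optn (-1.16 ± 0.21), and adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.00645, adjusted p = 0.392 with an estimated correlation). These counts depend on the scale. With TPM, 1 fission, 7 fusion and 1 mitophagy members were called lower.

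Part of the genes of heart muscle and energy metabolism were also lower. Nuclear-encoded subunits of oxidative phosphorylation fell in 47 of 76 cases, such as Cox8b (-0.96 ± 0.22) and Ndufb3 (-0.92 ± 0.18), and in 71 adjusted over the list alone (camera adjusted p = 3.93e-15, adjusted p = 0.563 with an estimated correlation). Genes of the tricarboxylic acid cycle fell in 10 of 17 cases, such as Idh2 (-1.17 ± 0.26), and in 13 adjusted over the list alone (camera adjusted p = 2.01e-05, adjusted p = 0.581 with an estimated correlation). For fatty acid oxidation 6 of 26 fell, such as Fabp3 (-1.16 ± 0.27), and 13 adjusted over the list alone (camera adjusted p = 0.000464, adjusted p = 0.796 with an estimated correlation). Contractile and calcium handling genes of heart muscle cells fell in 14 of 25 cases, such as Tcap (-1.58 ± 0.31), Myom2 (-1.42 ± 0.16) and Pln (-1.23 ± 0.26), and in 15 adjusted over the list alone (camera adjusted p = 7.18e-06, adjusted p = 0.563 with an estimated correlation). With TPM these 4 lists had 31, 6, 5 and 12 lower members. None of the 13 mitochondrially encoded genes was called by limma, with 0 also adjusted over the list alone, while camera called the list lower (camera adjusted p = 0.0494, adjusted p = 0.843 with an estimated correlation). Its median was -0.51, and camera's call was lost in 13 of 27 alternatives. With quantile normalization the median was 0, but that method gives genes of equal rank the same value in every library. It therefore cannot show a change of genes that keep their rank. Myh7, the slow myosin heavy chain gene, fell from 784 ± 446 to 107 ± 18.6 FPKM (log2 fold change -2.74, SE 0.36, adjusted p = 0.00292), and a gene on the opposite strand overlaps it.

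Some genes of infiltrating leukocytes rose at day 1. Arg1, an arginine-degrading enzyme of activated macrophages, rose from 0.290 ± 0.244 to 51.9 ± 31 FPKM (log2 fold change 5.18, SE 0.59, adjusted p = 0.00208). Spp1, which encodes osteopontin, rose from 17.9 ± 14.5 to 301 ± 81.6 FPKM (log2 fold change 4.29, SE 0.56, adjusted p = 0.00288). Slfn4 (4.76 ± 0.48), Plac8 (3.70 ± 0.77), Saa3 (3.65 ± 0.99) and Lcn2 (3.57 ± 0.69) were also among the 8 largest rises. Of the neutrophil markers 10 of 12 rose and G0s2 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.18e-06, adjusted p = 0.392 with an estimated correlation). Markers of monocytes and macrophages rose in 14 of 18 cases, such as Ccr2 (2.70 ± 0.52), and in 15 adjusted over the list alone (camera adjusted p = 1.97e-08, adjusted p = 0.392 with an estimated correlation). Repair-associated macrophage markers rose in 6 of 14 cases, and in 9 adjusted over the list alone (camera adjusted p = 6.21e-05, adjusted p = 0.392 with an estimated correlation). Resident macrophage markers rose in 4 of 12 cases, also adjusted over the list alone (camera adjusted p = 0.00838, adjusted p = 0.563 with an estimated correlation). Cytokine and chemokine genes rose in 16 of 20 cases, such as Cxcl5 (2.86 ± 0.22) and Ccl2 (2.52 ± 0.23), and in 17 adjusted over the list alone (camera adjusted p = 5.07e-10, adjusted p = 0.392 with an estimated correlation). Inflammasome and pyroptosis genes rose in 6 of 9 cases, such as Nlrp3 (1.09 ± 0.27), and in 8 adjusted over the list alone (camera adjusted p = 9.96e-05, adjusted p = 0.392 with an estimated correlation).

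Some genes of dividing cells and of the matrix rose as well. Of 24 cell cycle genes 24 rose, also adjusted over the list alone (camera adjusted p = 7.13e-16, adjusted p = 0.392 with an estimated correlation). Cdk1, the kinase that drives mitosis, went from 1.70 ± 0.623 to 11.1 ± 3.76 FPKM (adjusted p = 0.00207). Markers of activated fibroblasts rose in 11 of 20 cases, such as Tnc (3.23 ± 0.50), also adjusted over the list alone (camera adjusted p = 9.86e-06, adjusted p = 0.392 with an estimated correlation). Collagen genes rose in 9 of 18 cases, also adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.468 with an estimated correlation). Matrix proteases, inhibitors and crosslinkers rose in 13 of 21 cases, such as Timp1 (3.60 ± 0.54) and Lox (3.10 ± 0.37), and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 1.02e-05, adjusted p = 0.392 with an estimated correlation). Erythroid genes rose in 2 of 6 cases, and in 4 adjusted over the list alone (camera adjusted p = 0.0150, adjusted p = 0.626 with an estimated correlation). Heat shock genes fell in 3 of 19 cases, such as Hspb8 (-1.34 ± 0.20), and in 1 adjusted over the list alone (camera adjusted p = 0.0494, adjusted p = 0.843 with an estimated correlation), with the call of the list lost in 16 of 28 alternatives.

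Besides Myh7, the 8 largest falls were in Iigp1, Igtp, Gbp10, Gbp6, Irgm1, Irgm2 and Tgtp2, which encode GTPases of host defence that interferon induces. Iigp1 fell from 404 ± 109 to 23.8 ± 11 FPKM (log2 fold change -4.08, SE 0.31, adjusted p = 0.000902). Igtp fell from 294 ± 89.7 to 17.9 ± 8.37 FPKM (log2 fold change -4.01, SE 0.34, adjusted p = 0.000902). These families hold near-identical copies, Igtp and Irgm2 overlap on the same strand, and a predicted gene overlaps both Gbp6 and Gbp10, so the value of a single member is uncertain. The fixed list of interferon-stimulated genes had 2 and 2 of 20 members higher and lower, also adjusted over the list alone, and was not called (camera adjusted p = 0.312). Its called members included Oasl1 (1.45 ± 0.37) and Oas2 (1.11 ± 0.27). Camera called it higher in 2 of 28 alternatives, with array weights (adjusted p = 0.00811) and without day 1 replicate 3 (adjusted p = 0.000213), over a range of 0.000213 to 0.980.

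The other lists without a call at day 1 had camera adjusted p of 0.0503 to 0.975. Members higher and lower numbered 2 and 5 for glycolysis, 3 and 5 for hypoxia, 4 and 5 for oxidative stress defence, 3 and 3 for immediate early and 3 and 0 for complement genes. Adjusted over the list alone these were 2 and 7, 3 and 5, 4 and 6, 3 and 3 and 3 and 0. They numbered 1 and 2 for fetal and wall-stress, 2 and 1 for resting fibroblast, 1 and 0 for mesothelial, 1 and 1 for endothelial and 0 and 1 for pericyte and smooth muscle genes. Adjusted over the list alone these were 1 and 1, 2 and 1, 1 and 0, 0 and 0 and 0 and 0. No member was called by limma in the atrial, T and natural killer cell, mast cell, adipocyte, Schwann cell or skeletal muscle lists, with 0 also adjusted over the list alone. The atrial list had a median of 1.77, and camera called it higher in 5 of 28 alternatives. Complement was called higher in 6 of 28. Camera's direction was down for the oxidative stress list against a median of 0.07, and the hypoxia list had a median of -0.03 and a mean of 0.04.

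By limma, 1817 genes were higher and 1993 lower at day 1 than in sham, 528 and 175 of them by at least 2-fold. The groups did not overlap for 6430 genes, where chance gives 10%. Rescaling moved the median of all genes from -0.01 to 0.23 with TPM and 0.20 without mitochondrially encoded genes, and the share of calls that were higher from 47.7% to 80.3% and 80.2%. The higher count was 1000 without sham replicate 2 and 968 without day 1 replicate 2. The lower count was 1218 without sham replicate 1, 816 without sham replicate 2, 1215 without sham replicate 3, 1237 without day 1 replicate 1 and 790 without day 1 replicate 2. Without both libraries with airway markers, 256 genes were higher and 146 lower. AI662270, Hsp90b1 and Hspa5 then had adjusted p of 0.0620, 0.0534 and 0.0890 at log2 fold changes of 1.56, 0.71 and 0.59. These p were the highest over 25 alternatives, whose lowest were 0.00274, 0.000783 and 0.00211. The call was lost in 15 of 25 alternatives for Dnm1l, 9 of 25 for Mfn1, 4 of 25 for Mff and 1 of 25 for Mfn2.

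**Figure D1:**
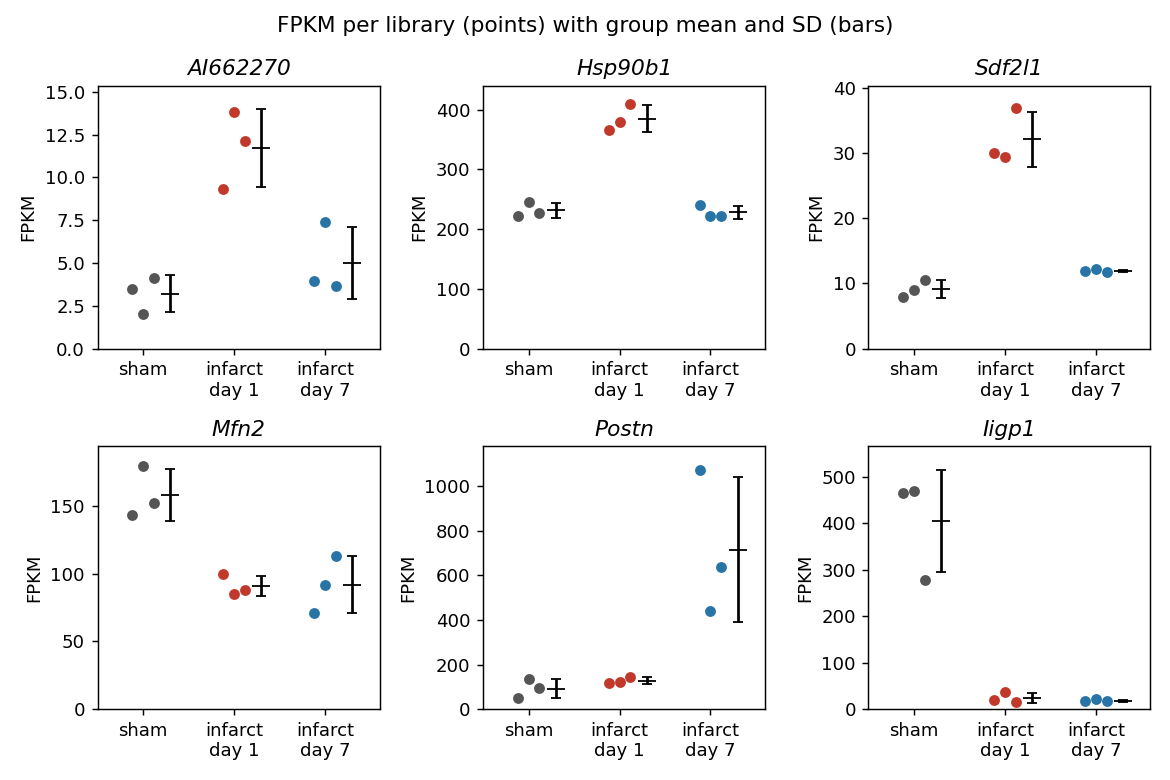
FPKM of 6 genes in each of the 9 libraries, in sham hearts and 1 and 7 days after infarction, with a point per library and bars for the mean ± SD of 3 libraries. AI662270 was at 3.21 in sham, 11.7 at day 1 and 5.0 at day 7, and Postn was at 91.3, 128 and 716.

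The comparison of day 7 with sham addresses the later heart. Genes of fibroblasts and matrix had the largest rises. Cthrc1, a secreted protein of activated fibroblasts, rose from 0.647 ± 0.521 to 57 ± 37.3 FPKM (log2 fold change 4.99, SE 0.44, adjusted p = 0.000905). The fibronectin gene Fn1 rose from 26.3 ± 6.57 to 421 ± 169 FPKM (log2 fold change 3.91, SE 0.28, adjusted p = 0.000481) and Col1a1 from 58 ± 17.2 to 821 ± 200.2 FPKM (log2 fold change 3.81, SE 0.23, adjusted p = 0.000209). Sfrp2 (4.54 ± 0.52), Ccn5 (4.16 ± 0.46), C1qtnf3 (3.92 ± 0.41), Lox (3.90 ± 0.37) and Mfap4 (3.63 ± 0.49) were the others of the 8 largest rises. Collagen genes rose in 17 of 18 cases, and in 18 adjusted over the list alone (camera adjusted p = 1.02e-12, adjusted p = 0.389 with an estimated correlation). Activated fibroblast markers rose in 18 of 20 cases, also adjusted over the list alone (camera adjusted p = 8.74e-13, adjusted p = 0.389 with an estimated correlation). Resting fibroblast markers rose in 7 of 14 cases, such as Cd248 (2.01 ± 0.11), and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.00353, adjusted p = 0.389 with an estimated correlation). Mesothelial and epicardial markers rose in 6 of 9 cases, such as Msln (2.36 ± 0.71), and in 7 adjusted over the list alone (camera adjusted p = 0.00146, adjusted p = 0.628 with an estimated correlation). Matrix protease and crosslinker genes rose in 11 of 21 cases and Timp4 fell (-1.37 ± 0.38), also adjusted over the list alone (camera adjusted p = 9.01e-06, adjusted p = 0.389 with an estimated correlation).

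Some macrophage genes were higher at day 7. Markers of monocytes and macrophages rose in 6 of 18 cases, such as Ms4a7 (2.20 ± 0.43) and Cd68 (1.09 ± 0.36), and in 7 adjusted over the list alone (camera adjusted p = 0.00520, adjusted p = 0.695 with an estimated correlation). Repair-associated markers rose in 8 of 14 cases, such as Ctsk (2.03 ± 0.34) and Igf1 (1.93 ± 0.31), and in 9 adjusted over the list alone (camera adjusted p = 2.25e-05, adjusted p = 0.628 with an estimated correlation). Resident macrophage markers rose in 5 of 12 cases, also adjusted over the list alone (camera adjusted p = 0.00855, adjusted p = 0.628 with an estimated correlation). Complement genes rose in 7 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.000264, adjusted p = 0.628 with an estimated correlation). Inflammasome genes rose in 3 of 9 cases, also adjusted over the list alone (camera adjusted p = 0.0379, adjusted p = 0.695 with an estimated correlation). Of these calls, camera's was lost in 12 of 28 alternatives for the inflammasome, 5 of 28 for monocytes and macrophages, 4 of 28 for resident macrophages, 1 of 28 for repair-associated macrophages and 2 of 28 for complement. Cell cycle genes rose in 23 of 24 cases, such as Cdk1 (1.56 ± 0.24), also adjusted over the list alone (camera adjusted p = 2.32e-09, adjusted p = 0.628 with an estimated correlation). Erythroid genes rose in 5 of 6 cases, also adjusted over the list alone (camera adjusted p = 0.00688, adjusted p = 0.628 with an estimated correlation). Among 12 neutrophil markers, Clec4d rose (2.0 ± 0.28) and G0s2 fell (-0.85 ± 0.25), also adjusted over the list alone (camera adjusted p = 0.524).

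AI662270, Hsp90b1 and Hspa5 did not pass the test at day 7. AI662270 was at 5.0 ± 2.08 FPKM (log2 fold change 0.49, SE 0.27, adjusted p = 0.183), Hsp90b1 at 228 ± 10.9 (log2 fold change -0.02, SE 0.10, adjusted p = 0.896) and Hspa5 at 212 ± 12.3 (log2 fold change -0.18, SE 0.12, adjusted p = 0.286). Hdc did not pass either (adjusted p = 0.832). Of the ER chaperones and folding enzymes 8 of 22 rose, such as Txndc5 (1.06 ± 0.20) and Pdia4 (0.65 ± 0.09), and 2 fell, such as Dnajb9 (-0.66 ± 0.10). Adjusted over the list alone, 10 rose and 2 fell (camera adjusted p = 0.00858, adjusted p = 0.695 with an estimated correlation). For ER-associated degradation 3 of 16 rose, also adjusted over the list alone (camera adjusted p = 0.389). Of the ER stress sensors and factors 3 rose and 7 fell, such as Ddit3 (-1.26 ± 0.27) and Ddit4 (-1.0 ± 0.21), also adjusted over the list alone (camera adjusted p = 0.203).

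Part of the mitochondrial dynamics genes were below sham at day 7. Dnm1l fell from 42.7 ± 2.98 to 28.2 ± 3.99 FPKM (log2 fold change -0.59, SE 0.11, adjusted p = 0.00848) and Mfn2 from 158 ± 18.9 to 91.8 ± 21 FPKM (log2 fold change -0.80, SE 0.17, adjusted p = 0.0113). Mff and Mfn1 fell too (-0.50 ± 0.12 and -0.83 ± 0.21, adjusted p = 0.0181 and 0.0202). Fis1 and Opa1 did not pass (adjusted p = 0.871 and 0.0661). In the fission list 3 of 9 fell, also adjusted over the list alone (camera adjusted p = 0.0244, adjusted p = 0.628 with an estimated correlation), but its median of -0.25 became 0.08 with TPM, as the median of all genes rose. Relative to all genes it was -0.24 and -0.22, and the camera call was lost in 6 of 28 alternatives. For fusion and inner membrane shape 11 of 15 fell, and 14 adjusted over the list alone (camera adjusted p = 1.20e-05, adjusted p = 0.628 with an estimated correlation). For mitophagy 4 of 14 fell, also adjusted over the list alone (camera adjusted p = 0.0887). Oxidative phosphorylation subunits fell in 44 of 76 cases, and in 59 adjusted over the list alone (camera adjusted p = 5.70e-12, adjusted p = 0.648 with an estimated correlation). Tricarboxylic acid cycle genes fell in 13 of 17 cases, and in 17 adjusted over the list alone (camera adjusted p = 3.66e-06, adjusted p = 0.628 with an estimated correlation). Contractile genes fell in 12 of 25 cases, and in 19 adjusted over the list alone (camera adjusted p = 9.01e-06, adjusted p = 0.628 with an estimated correlation). For fatty acid oxidation 12 of 26 fell and Cpt1a rose, with 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000218, adjusted p = 0.695 with an estimated correlation). With TPM, lower members numbered 4 for fusion, 16 for oxidative phosphorylation, 9 for the tricarboxylic acid cycle, 6 for contraction and 8 for fatty acid oxidation. Of the mitochondrially encoded genes mt-Nd4l fell (-0.96 ± 0.28), and 0 of 13 did adjusted over the list alone (camera adjusted p = 0.0268, adjusted p = 0.738 with an estimated correlation), with camera's call lost in 11 of 27 alternatives.

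The largest falls at day 7 were in Igtp (-4.58 ± 0.34), Gbp10 (-4.50 ± 0.35), Iigp1 (-4.39 ± 0.31), Hsp90aa1, Rpl12, Gbp6 (-3.80 ± 0.32), Snurf and Irgm1 (-3.38 ± 0.32). Hsp90aa1 was at 36.9 ± 61.3 FPKM against 170.4 ± 66.5 in sham (log2 fold change -4.22, SE 1.25, adjusted p = 0.0333). The ribosomal protein gene Rpl12 was at 80.2 ± 133 FPKM against 289 ± 24.8 (log2 fold change -4.08, SE 1.29, adjusted p = 0.0403). In day 7 replicates 1 and 2, Hsp90aa1 was at 1.71 and 1.31 FPKM and Rpl12 at 3.39 and 3.88, while replicate 3 had 108 and 233. Snurf, which overlaps Snrpn on the same strand and is therefore uncertain, was at 0.0181 ± 0.0242 FPKM against 13.7 ± 5.12 (log2 fold change -3.80, SE 0.84, adjusted p = 0.0124). Interferon-stimulated genes fell in 4 of 20 cases, such as Irf7 (-2.62 ± 0.48), also adjusted over the list alone (camera adjusted p = 0.00152, adjusted p = 0.712 with an estimated correlation). Heat shock genes fell in 14 of 19 cases, such as Hspd1 (-0.96 ± 0.19), and in 16 adjusted over the list alone (camera adjusted p = 5.71e-06, adjusted p = 0.628 with an estimated correlation).

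Lists without a camera call at day 7 had adjusted p of 0.0887 to 0.668. Members higher and lower numbered 3 and 1 for cytokines, 1 and 4 for glycolysis, 2 and 5 for oxidative stress defence and 2 and 0 for immediate early genes. Adjusted over the list alone they numbered 2 and 1, 1 and 3, 2 and 7 and 0 and 0. For hypoxia, fetal, endothelial, pericyte and mast cell genes they were 0 and 3, 0 and 2, 1 and 2, 3 and 1 and 1 and 0, also adjusted over the list alone. The atrial, T and natural killer cell, adipocyte, Schwann cell and skeletal muscle lists had 0 called by limma, also adjusted over the list alone.

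By limma, 2127 genes were higher and 2341 lower at day 7 than in sham, 477 and 195 of them by at least 2-fold. The groups did not overlap for 7260 genes, where chance gives 10%. The median of all genes moved from -0.02 to 0.30 with TPM and 0.19 without mitochondrially encoded genes, and the share of calls that were higher from 47.6% to 87.8% and 78.7%. The higher count was 1417 without sham replicate 1, 1124 without sham replicate 2 and 1279 without day 7 replicate 1. The lower count was 1517 without sham replicate 1, 1042 without sham replicate 2, 1500 without sham replicate 3 and 1307 without day 7 replicate 1. Without day 7 replicates 1 and 2, which leaves 1 library assumed to vary like the other groups, 146 genes were higher and 56 lower. Without the airway-marker libraries the counts were 1078 and 1047. The call was lost in 11 of 25 alternatives for Hsp90aa1, 15 of 25 for Rpl12, 6 of 25 for Mff, 4 of 25 for Mfn1 and 2 of 25 for Dnm1l.

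**Figure D2:**
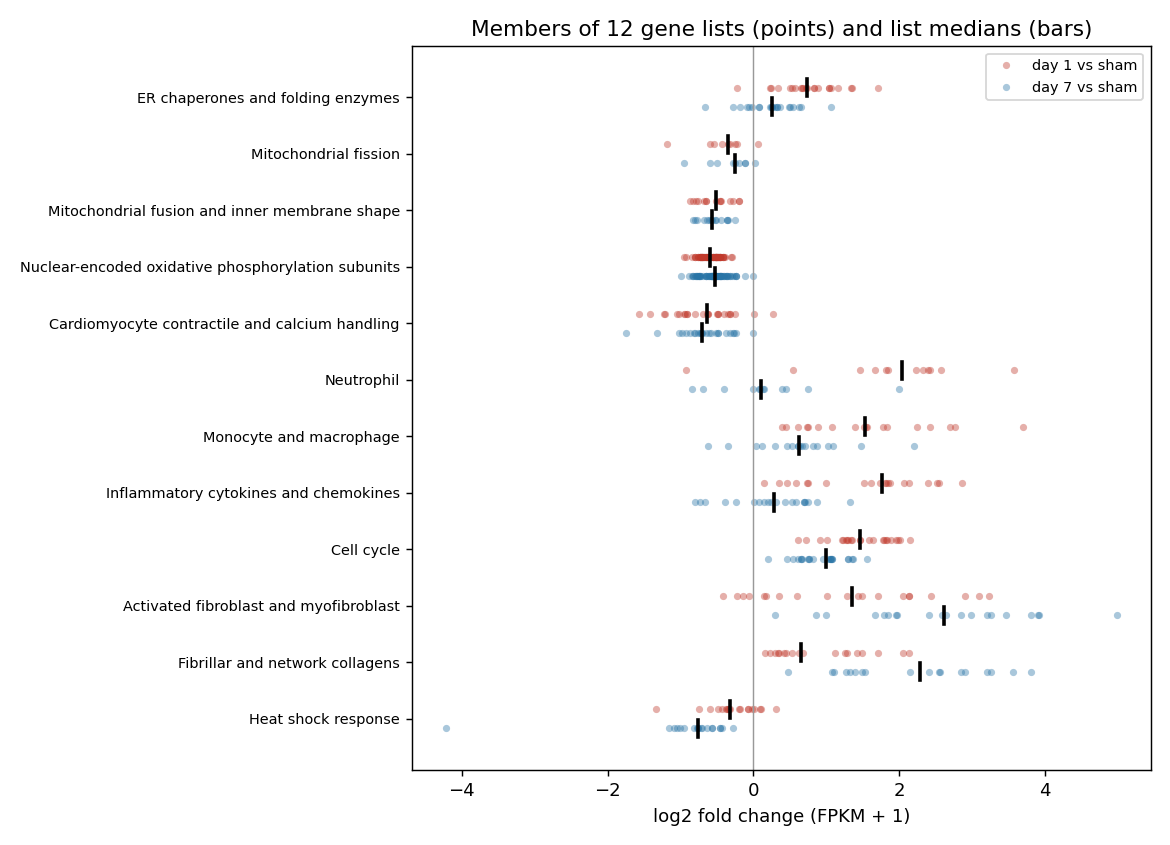
Log2 fold changes of the tested members of 12 gene lists against sham, at day 1 (red) and day 7 (blue) after infarction, with a point per gene and black bars for medians. Medians at day 1 and day 7 were 0.73 and 0.26 for ER chaperones, 2.04 and 0.11 for neutrophil markers and 0.65 and 2.28 for collagens.

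The direct comparison of day 7 with day 1 separates early from late changes. Hsp90b1 and Hspa5 fell between the times (-0.75 ± 0.10 and -0.75 ± 0.12, adjusted p = 0.00864 and 0.0195). AI662270 did not pass the test (log2 fold change -1.12, SE 0.27, adjusted p = 0.0515). ER chaperones and folding enzymes fell in 13 of 22 cases, such as Sdf2l1 (-1.35 ± 0.12), and in 19 adjusted over the list alone (camera adjusted p = 7.17e-14, adjusted p = 0.316 with an estimated correlation). Of the ER stress sensors and factors 2 of 21 fell, Cebpb (-0.74 ± 0.15) and Xbp1 (-0.41 ± 0.10), and 5 adjusted over the list alone (camera adjusted p = 0.0405, adjusted p = 0.739 with an estimated correlation). Camera's call of this list was lost in 10 of 28 alternatives. For ER-associated degradation 0 fell, and 2 adjusted over the list alone (camera adjusted p = 0.0572). Dnm1l, Mff, Mfn1 and Mfn2 had adjusted p of 0.257, 0.850, 0.883 and 0.984, and Fis1, Opa1 and Hdc of 0.104, 0.688 and 0.378.

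Some inflammatory genes fell from day 1 to day 7, and some collagen and fibroblast genes rose. Slfn4 fell from 78 ± 49.3 to 1.67 ± 0.512 FPKM (log2 fold change -4.71, SE 0.48, adjusted p = 0.00309), Ms4a4c from 122 ± 53.2 to 7.83 ± 1.40 (log2 fold change -3.72, SE 0.41, adjusted p = 0.00434) and the chemokine gene Ccl7 from 58.3 ± 8.02 to 5.61 ± 2.28 (log2 fold change -3.21, SE 0.28, adjusted p = 0.00186). Slfn4 and Ccl7 belong to families of similar genes and are uncertain. Cytokine and chemokine genes fell in 8 of 20 cases, and in 14 adjusted over the list alone (camera adjusted p = 5.49e-10, adjusted p = 0.316 with an estimated correlation). Neutrophil markers fell in 6 of 12 cases, and in 9 adjusted over the list alone (camera adjusted p = 2.34e-08, adjusted p = 0.316 with an estimated correlation). Monocyte and macrophage markers fell in 4 of 18 cases, and in 10 adjusted over the list alone (camera adjusted p = 8.39e-05, adjusted p = 0.710 with an estimated correlation). Interferon-stimulated genes fell in 3 of 20 cases, and in 13 adjusted over the list alone (camera adjusted p = 4.80e-09, adjusted p = 0.710 with an estimated correlation). Inflammasome genes fell in 1 of 9 cases, and in 4 adjusted over the list alone (camera adjusted p = 0.00964, adjusted p = 0.710 with an estimated correlation). Heat shock genes fell in 4 of 19 cases, and in 7 adjusted over the list alone (camera adjusted p = 0.000222, adjusted p = 0.710 with an estimated correlation). No cell cycle gene was called over all genes, 13 of 24 were lower adjusted over the list alone, and the median was -0.55 (camera adjusted p = 2.12e-08, adjusted p = 0.710 with an estimated correlation).

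C1qtnf3 rose from 0.135 ± 0.0915 to 19.8 ± 13.8 FPKM (log2 fold change 3.97, SE 0.41, adjusted p = 0.00309) and Col11a1 from 0.571 ± 0.270 to 17.4 ± 13.4 FPKM (log2 fold change 3.33, SE 0.40, adjusted p = 0.00662). Activated fibroblast markers rose in 12 of 20 cases, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 1.01e-09, adjusted p = 0.316 with an estimated correlation). Collagens rose in 10 of 18 cases, and in 13 adjusted over the list alone (camera adjusted p = 2.44e-11, adjusted p = 0.316 with an estimated correlation). Resting fibroblast markers rose in 6 of 14 cases, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 7.95e-05, adjusted p = 0.316 with an estimated correlation). Mesothelial markers rose in 2 of 9 cases, and in 4 adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.710 with an estimated correlation). Dbp, a transcription factor under the circadian clock, rose from 1.90 ± 0.374 to 30.1 ± 3.34 FPKM (log2 fold change 3.42, SE 0.29, adjusted p = 0.00186).

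The remaining lists had camera adjusted p of 0.0572 to 0.963. Members higher and lower numbered 4 and 3 for matrix proteases, 1 and 1 for repair-associated macrophages, 1 and 1 for complement and 1 and 0 for immediate early genes. Adjusted over the list alone they numbered 7 and 5, 2 and 3, 2 and 1 and 3 and 0. They were 0 and 1 for glycolysis, 0 and 1 for hypoxia and 0 and 0 for resident macrophages, against 0 and 2, 0 and 2 and 2 and 0 adjusted over the list alone. They were 1 and 0 for pericytes, 0 and 1 for fetal genes and 0 and 1 for oxidative stress defence, also adjusted over the list alone. The mitochondrial, metabolic, contractile and other cell type lists not named here had 0 called by limma, also adjusted over the list alone, while camera called oxidative phosphorylation higher in 5 of 28 alternatives. Medians were 0.03 for contractile and 0.01 for glycolysis genes where camera's direction was down. They were -0.14 for resident macrophages and -0.10 for matrix proteases where it was up, and repair-associated macrophages had a median of 0.09 and a mean of -0.09.

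By limma, 366 genes were higher and 289 lower at day 7 than at day 1, 120 and 107 of them by at least 2-fold. The groups did not overlap for 3671 genes, where chance gives 10%. In a fit of these 2 groups alone the counts were 78 and 88. The higher count was 211 without sham replicate 1, 221 without sham replicate 3, 175 without day 1 replicate 1, 75 without day 1 replicate 2, 160 without day 7 replicate 1 and 102 without day 7 replicate 3. The lower count was 150 without sham replicate 1, 192 without sham replicate 3, 177 without day 1 replicate 1, 62 without day 1 replicate 2, 114 without day 7 replicate 1, 160 without day 7 replicate 2 and 89 without day 7 replicate 3. Without the airway-marker libraries 34 and 26 genes were called, and without day 7 replicates 1 and 2 19 and 8. The call was lost in 3 of 25 alternatives for Hsp90b1 and 6 of 25 for Hspa5.

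Across the 3 groups 5053 genes differed by limma's F test. Of the genes called, 182 rose at day 1 and were lower at day 7 than at day 1, among them Hsp90b1 and Ccl2, and 282 were higher at day 7 than in sham and at day 1, among them Col1a1 and Sfrp2. A further 59 were lower at day 1 than in sham and than at day 7, such as Nr4a1 and Dbp, and 80 were lower at day 7 than in sham and at day 1, such as Hsph1. Each gene was counted once, and a gene that met the rules of both a rise and a fall was counted as a fall. The 182 and 282 leave such genes out, among them Dbp, which was also higher at day 7 than in sham. With no call between the times, 980 genes were higher than sham at both, such as Cdk1 and Tnc, and 1369 were lower at both, such as Mfn2 and Iigp1. Log2 fold changes at day 1 and day 7 correlated across genes, which are not independent replicates, at 0.718. Simulated groups with no effect that share the 3 sham libraries gave 0.499. The covariance was 0.210 against a simulated 0.0279. In both comparisons 1046 genes were called higher and 1379 lower, against 0 and 0 in the simulation and 286 and 345 for independent lists of these sizes. The simulation held no effect in any gene, so hardly any gene could be called in it. Its 0 and 0 therefore do not measure the overlap that shared controls create. The same sign was found for 79.8% of genes, against 66.6% simulated. With 3 sham libraries the controls could not be split into parts of at least 2, so part of the excess over independent lists may come from sharing them.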

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

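The tests of the clock genes were chosen only after the result was seen, while the comparison of day 7 with day 1 was planned. The lists and genes here drew attention because their change from sham differed between the times, by limma for genes and camera for lists. Median log2 fold changes from day 1 to day 7 were -1.86 for neutrophil markers, -1.32 for cytokines and chemokines, -1.19 for interferon-stimulated genes, -0.93 for monocyte and macrophage markers, -0.61 for ER chaperones and folding enzymes, -0.55 for cell cycle genes, -0.55 for heat shock genes, -0.43 for inflammasome genes and -0.18 for ER stress sensors and factors. They were 1.45 for activated fibroblast markers, 1.16 for collagens, 1.10 for mesothelial markers and 0.71 for resting fibroblast markers. With an estimated correlation camera called 0 lists between the times, with unadjusted p under 0.05 for 6.

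Among inflammatory and leukocyte genes the log2 fold changes from day 1 to day 7 were -4.71 for Slfn4, -3.72 for Ms4a4c, -3.44 for Lcn2, -3.21 for Ccl7, -2.96 for Slfn1, -2.90 for Ccl2, -2.72 for Chil3 and -2.61 for Ccl12. They were -2.54 for S100a9, -2.40 for Cxcr2, -2.33 for Cxcl5, -2.30 for Fcgr1, -2.27 for Il1r2, -1.83 for Ifi44, -1.71 for Cd300lf, -1.68 for Oasl1, -1.48 for Ms4a6c, -1.28 for Oas2, -1.16 for Nlrp3 and -0.94 for C5ar1. For genes of protein folding and stress they were -1.35 for Sdf2l1, -1.08 for Hsph1, -0.91 for Pdia6, -0.80 for Creld2, -0.77 for Hspa8, -0.75 for Hspa5, -0.75 for Hsp90b1, -0.74 for Cebpb, -0.74 for Chordc1, -0.55 for Hsp90ab1 and -0.41 for Xbp1. Metabolic and protective genes had -2.24 for Hmox1, -1.42 for Mt2 and -1.22 for Slc16a3, and the protease gene Adamts4 had -1.73.

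Rises in matrix and stromal genes were 3.97 for C1qtnf3, 3.33 for Col11a1, 3.33 for Sfrp2, 3.12 for Angptl7, 3.02 for Ccn5, 2.74 for Itgbl1 and 2.66 for Col8a2. Further values were 2.45 for Ltbp2, 2.38 for Thbs2, 2.38 for Postn, 2.09 for Cthrc1, 1.92 for Col16a1, 1.93 for Muc16, 1.86 for Col14a1, 1.78 for Mfap5, 1.67 for Col1a1, 1.56 for Mmp2, 1.55 for Adamts2, 1.40 for Pi16, 1.18 for Cd248, 1.12 for Col15a1 and 1.11 for Timp2. Genes of other kinds had 3.42 for Dbp, 1.14 for Nr4a1, 0.98 for Apoe, 0.92 for Serping1, 0.73 for Notch3 and 0.73 for Wt1.

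Dbp belongs to the output of the circadian clock, and 17 genes of the clock were looked at for that reason. From day 1 to day 7, 8 of 11 genes that go with Dbp in the clock rose and 4 of 6 that go with Arntl fell (medians 1.15 and -1.09), while at day 1 against sham 8 of the first set were lower and 2 of the second were higher, and at day 7 against sham 5 of the first were higher and 4 of the second lower (medians 0.42 and -0.83). The sets were drawn up after the values had been seen, at first without 3 of these genes. The contractile genes, a list fixed beforehand, moved by a median of 0.03 and the genes that go with Dbp by 1.12 more. The clock genes were looked at because Dbp was among the largest rises between the times. The difference of 1.12 was thus settled in part by the selection, and it cannot decide on a changing share of heart muscle. The sets moved apart by 2.25, which the hour of tissue collection could produce and so could an effect of infarction on the clock, and these cannot be told apart because the hour is not among the labels.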

How the results depend on the processing

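Leaving out pairs of libraries, the most expressed transcript and the atrial score were tests chosen only after the result was seen, and the others were planned. Over the alternatives, named genes kept direction and side of the threshold in 6961 cases, lost the call in 1410, gained one in 20 and reversed in 0. Lists kept theirs in 3114, lost it in 153, gained it in 76 and reversed in 5. Counts stayed within 1.5 times in 345 cases and moved further in 141. A filter tests fewer genes, a block or covariate leaves fewer degrees of freedom and a left-out library leaves fewer samples. In no setting was the cause of a change tested. Library depth is unknown, so what it limits could not be measured.

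With an estimated correlation camera called 0 lists higher and 0 lower in each comparison, against unadjusted p under 0.05 for 3, 4 and 6 lists. Adjusted p was then 0.392 for ER chaperones, ER-associated degradation, fission and mitophagy and 0.486 for fusion at day 1. It was 0.695 for ER chaperones and 0.628 for fission and fusion at day 7, and 0.316 for ER chaperones and 0.739 for ER stress sensors between the times. Fry, which tests a list by itself, called 11 lists higher and 5 lower at day 1, 7 and 6 at day 7 and 4 and 3 between the times. Its adjusted p at day 7 was 0.0611 for ER chaperones and 0.0243 for mitophagy, and between the times 0.262 for ER stress sensors, whose adjusted p by camera on ranks was 0.0647.

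Over all alternatives adjusted p ranged over 5.34e-05 to 0.695 for ER chaperones, 0.0179 to 0.628 for fission, 6.68e-08 to 0.628 for fusion, 0.0243 to 0.628 for mitophagy and 0.0295 to 0.738 for ER stress sensors at day 7. At day 1 it was 3.24e-16 to 0.392 for ER chaperones, 0.00254 to 0.392 for ER-associated degradation, 0.00109 to 0.392 for fission, 4.61e-08 to 0.486 for fusion and 0.000684 to 0.392 for mitophagy. Between the times it was 9.96e-18 to 0.316 for ER chaperones, 0.0129 to 0.739 for ER stress sensors, 0.00606 to 0.702 for ER-associated degradation, 0.0362 to 0.950 for fission and 0.0338 to 0.739 for mitophagy. Adjusted p of fission at day 7 was 0.0769 with the filter at 5 FPKM, 0.159 with quantile normalisation, 0.123 with TPM, 0.0673 without mitochondrially encoded genes and 0.0539 with the most expressed transcript. For mitophagy it was 0.0298 at day 7 without a filter and 0.0567 at day 1 with quantile normalisation. For ER stress sensors it was 0.0295 at day 7 with TPM, and between the times 0.293 with the filter at 5, 0.0513 with the most expressed transcript and 0.0787 without airway-marker libraries. For ER-associated degradation between the times it was 0.0225 with array weights and 0.0344 with the most expressed transcript.

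Without a filter there were 49 late falls. With the filter at 5 FPKM, counts were 1199 higher at day 1, 1310 higher at day 7 and 242 higher between the times, with 113 early rises and 177 late rises. With TPM they were 601 lower at day 1, 3809 higher and 527 lower at day 7 and 113 higher and 72 lower between the times, with 61 early rises, 87 late rises, 23 early falls, 8 late falls, 1729 higher at both times and 300 lower at both times. Without mitochondrially encoded (mt) genes they were 3583 higher and 886 lower at day 1 and 3844 higher and 1042 lower at day 7, with 32 early falls, 2294 higher at both times and 513 lower at both times. Array weights gave 3027 lower at day 1 and 584 higher and 466 lower between the times, with 306 early rises, 191 early falls and 123 late falls. The atrial score gave 1112 lower at day 1, with 613 higher at both times and 721 lower at both times. A fit of 2 groups alone gave 78 higher and 88 lower between the times.

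Replicate numbers did not pair the samples. Correlations of the deviations of same-numbered libraries were 0.27, -0.37, 0.23 for day 1 and sham, -0.07, -0.26, -0.13 for day 7 and sham and 0.05, 0.23, 0.18 for day 7 and day 1. With the replicate number as a block, 144 higher and 93 lower between the times were called, with 67 early rises, 119 late rises, 25 early falls and 25 late falls. Of the calls without a block it kept 2942 of 3810 at day 1, 3499 of 4468 at day 7 and 229 of 655 between the times, and a lost call is no weaker effect.

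Without the airway-marker libraries the counts were 256 higher and 146 lower at day 1, 1078 higher and 1047 lower at day 7, 34 higher and 26 lower between the times and 951 by the F test, with 17 early rises, 28 late rises, 5 early falls, 7 late falls, 144 higher at both times and 114 lower at both times, and 63.7% of the day 1 calls were higher. Without day 7 replicates 1 and 2, with the lone library assumed to vary like the others, they were 146 higher and 56 lower at day 7, 19 higher and 8 lower between the times and 2767 by the F test, with 8 early rises, 13 late rises, 6 early falls, 0 late falls, 93 higher at both times and 52 lower at both times by limma, where late falls at unadjusted p under 0.05 were 167. Of the day 7 calls 72.3% were then higher, and the correlation of day 1 and day 7 changes was 0.627. In that setting 9 lists were higher between the times. Adjusted p was 0.0116 for ER-associated degradation and 0.0338 for mitophagy, and the direction of fatty acid oxidation (0.000513, range 5.99e-05 to 0.950), the tricarboxylic acid (TCA) cycle (0.0484, range 0.00265 to 0.950) and contractile genes (0.00146, range 0.00146 to 0.996) reversed to higher.

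Leaving out 1 library at a time (rep for replicate), with counts that moved over 1.5 times below, genes higher and lower ranged over 968 to 1957 and 790 to 2299 at day 1, 1124 to 2276 and 1042 to 2618 at day 7 and 75 to 275 and 62 to 244 between the times. The F test ranged over 2419 to 5353, lists higher between the times over 4 to 10, early rises over 46 to 165, late rises over 61 to 231, early falls over 14 to 74, late falls over 15 to 76 and genes higher and lower at both times over 369 to 994 and 450 to 1537. Without sham rep 1 there were 1218 lower at day 1, 1417 higher and 1517 lower at day 7, 211 higher and 150 lower between the times and 3011 by the F test, with 106 early rises, 161 late rises, 27 early falls, 33 late falls, 552 higher at both times and 784 lower at both times. Without sham rep 2 there were 1000 higher and 816 lower at day 1, 1124 higher and 1042 lower at day 7 and 2419 by the F test, with 31 early falls, 39 late falls, 369 higher at both times and 450 lower at both times. Without sham rep 3 there were 1215 lower at day 1, 1500 lower at day 7, 221 higher and 192 lower between the times and 3115 by the F test, with 160 late rises, 33 early falls, 37 late falls and 761 lower at both times. Without day 1 rep 1 there were 1237 lower at day 1 and 175 higher and 177 lower between the times, with 133 late rises, 35 early falls, 35 late falls and 889 lower at both times. Without day 1 rep 2 there were 968 higher and 790 lower at day 1 and 75 higher and 62 lower between the times, with 47 early rises, 61 late rises, 14 early falls, 15 late falls, 573 higher at both times and 618 lower at both times. Without day 1 rep 3 there were 175 late rises. Without day 7 rep 1 there were 1279 higher and 1307 lower at day 7 and 160 higher and 114 lower between the times, with 90 early rises, 106 late rises and 21 late falls, with 10 lists higher between the times. Without day 7 rep 2 there were 160 lower between the times, with 31 early falls and 29 late falls. Without day 7 rep 3 there were 102 higher and 89 lower between the times, with 46 early rises, 81 late rises, 20 early falls and 43 late falls, with 7 lists higher between the times.

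Leaving out 1 library, adjusted p of lists ranged from 0.0359 without sham rep 3 to 0.330 without day 7 rep 3 for ER stress sensors at day 7. Between the times it ranged from 0.00606 without day 7 rep 1 to 0.153 without day 7 rep 2 for ER-associated degradation, from 0.0203 without day 1 rep 1 to 0.0744 without day 1 rep 3 for ER stress sensors (0.0721 without day 1 rep 2, 0.0589 without day 7 rep 2 and 0.0702 without day 7 rep 3) and from 0.0362 without day 7 rep 1 to 0.619 without day 1 rep 2 for fission. It ranged from 5.99e-05 without day 7 rep 1 to 0.783 without day 1 rep 1 for fatty acid oxidation and from 0.0354 without day 7 rep 1 to 0.989 without sham rep 2 for contractile genes, and both reversed to higher without day 7 rep 1.

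In the other lists, alternatives that lost the call, where 3 or more, numbered (with the range of adjusted p) 13 for mt genes (0.000999 to 0.843), 5 for erythroid genes (0.000478 to 0.626) and 16 for heat shock (0.00412 to 0.843) at day 1. They were 11 for mt genes (7.07e-05 to 0.807), 5 for monocytes and macrophages (3.28e-05 to 0.695), 4 for resident macrophages (0.000923 to 0.628), 3 for erythroid genes (0.00109 to 0.628) and 12 for inflammasome (0.0135 to 0.695) at day 7. They were 5 for mesothelium (2.01e-05 to 0.710) and 5 for inflammasome (0.000513 to 0.710) between the times. Alternatives that gained a call numbered 1 for glycolysis (0.0362 to 0.919), 5 for atrial genes (0.000540 to 0.962), 1 for adipocytes (0.0341 to 0.997), 3 for mesothelium (0.0158 to 0.843), 2 for interferon-stimulated genes (0.000213 to 0.980) and 6 for complement (0.000365 to 0.836) at day 1. They were 2 for glycolysis (0.0329 to 0.954), 4 for fetal genes (0.00903 to 0.738) and 1 for skeletal muscle (0.0239 to 0.829) at day 7. They were 5 for oxidative phosphorylation (1.20e-08 to 0.950), 1 for fatty acid oxidation (5.99e-05 to 0.950), 1 for TCA cycle (0.00265 to 0.950), 1 for atrial genes (0.00219 to 0.950), 4 for T and killer cells (0.0103 to 0.950), 1 for endothelium (0.0159 to 0.950), 3 for pericytes (0.0371 to 0.344), 7 for skeletal muscle (0.00126 to 0.811), 7 for hypoxia (0.00290 to 0.908) and 11 for complement (0.00599 to 0.908) between the times. Gained calls were lower for glycolysis, fetal genes and hypoxia and, between the times, fatty acid oxidation, TCA cycle and atrial genes, and higher for the rest.

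With 1 library left out, calls of these lists changed to these adjusted p. Without sham rep 1 p was 0.0810 for mt genes, 0.0158 for atrial genes, 0.0341 for adipocytes, 0.0158 for mesothelium and 0.0141 for complement at day 1, 0.0571 for mt genes and 0.0421 for fetal genes at day 7. Without sham rep 2 p was 0.460 for heat shock at day 1, 0.118 for inflammasome at day 7, 0.0489 for complement between the times. Without sham rep 3 p was 0.0758 for mt genes and 0.0296 for complement at day 1. Without day 1 rep 1 p was 0.103 for mt genes and 0.0923 for heat shock at day 1, 0.00290 for hypoxia and 0.00710 for complement between the times. Without day 1 rep 2 p was 0.173 for mt genes and 0.173 for heat shock at day 1, 0.0103 for T and killer cells, 0.0721 for inflammasome and 0.0103 for complement between the times. Without day 1 rep 3 p was 0.0362 for glycolysis, 0.000540 for atrial genes, 0.0539 for erythroid genes, 0.0197 for mesothelium, 0.000213 for interferon-stimulated genes and 0.000365 for complement at day 1, 0.00413 for oxidative phosphorylation, 0.00219 for atrial genes, 0.0159 for endothelium and 0.150 for mesothelium between the times. Without day 7 rep 1 p was 0.0558 for heat shock at day 1, 0.108 for mt genes at day 7, 1.20e-08 for oxidative phosphorylation, 0.0354 for T and killer cells, 0.0226 for skeletal muscle and 0.0354 for hypoxia between the times. Without day 7 rep 2 p was 0.0573 for mt genes and 0.0539 for heat shock at day 1, 0.0635 for resident macrophages and 0.143 for inflammasome at day 7, 0.0484 for pericytes between the times. Without day 7 rep 3 p was 0.0648 for heat shock at day 1, 0.0329 for glycolysis and 0.0239 for skeletal muscle at day 7, 0.0478 for fatty acid oxidation, 0.00265 for TCA cycle, 0.0317 for T and killer cells, 0.00126 for skeletal muscle, 0.0317 for hypoxia and 0.0396 for complement between the times.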

Other observations

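The tests of the interferon-induced and of the nearly absent genes were chosen only after the result was seen, while the other splits of the samples were planned. Of 17 tested genes for immunity-related GTPases and guanylate-binding proteins, which interferon gamma induces, 14 were lower than sham at day 1 and 14 at day 7 (medians -2.01 and -2.02), and their FPKM summed to 1662, 1761 and 1091 in sham, 195, 315 and 130 at day 1 and 153, 176 and 155 at day 7. Among 15 other genes that interferon gamma induces, such as B2m and Psmb10, 11 were lower at day 1 and 11 at day 7 (medians -1.04 and -1.19), in sets drawn up after the values had been seen. The median of the GTPase genes at day 1 minus that of the contractile genes was -1.37. The set was drawn up because the largest falls at day 1 besides Myh7 were among its members. This difference was thus settled in part by the selection, and it cannot decide on a lower share of heart muscle. Reads moving among these 17 genes are argued against, since the lowest sham sum was 3.46 times the highest day 1 sum. Reads moving to copies outside the sum, such as the predicted gene that overlaps Gbp6 and Gbp10, were not tested. In 15 of the 17 genes every sham library lay above every infarct library, which an immune state or handling of the sham animals may produce as well as infarction, and these cannot be told apart with 1 sham group whose day is not given.

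In day 7 replicates 1 and 2, 10 expressed genes were nearly absent, below 20% of the lowest of the other 7 libraries, and 2 or fewer were in any other pair. They were Rrp15, Rrp7a, Hsp90aa1, Rrp36, Cmtr1, Rrp12, Rpl12, Rrp1, Exosc5 and Gm26917, in a definition that replaced a first one (below 10% of the mean) after the values were seen. Too few reads are argued against, since of 4621 genes at a mean under 5 FPKM, which were not searched, 0.281% were below 10% of it in both libraries, in a test that replaced 2 others after their results were seen, the first of which left this open. An effect of infarction at day 7 cannot be told apart from a technical loss, since only replicate 3 is left to compare: over 12 genes chosen without it, it had a median of 0.851 times the sham mean, in a test that also replaced another. Removal of reads that matched a list of sequences with names like those of ribosomal RNA may explain part of it and stays open, since of 12 expressed genes with an Rrp or Rrn name, 41.7% were below 10% of the mean, against 0 of 36 ribosome biogenesis genes without one. The 41.7% were the genes that prompted this explanation, so the share in part restates the loss. It also stayed below the share that the test required.

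The 6 libraries of a comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. At day 1 against sham, 1817 higher and 1993 lower genes were reached by 1 split, the real one, and the highest other count was 25. At day 7 against sham 2127 and 2341, and at day 7 against day 1 366 and 289, were also reached by 1 split, with a highest other count by limma of 0. Counts of lists were reached by other splits too. The 13 lists called higher and 9 lower at day 1 were reached by 4 and 8 splits, with up to 16 lists in another. The 13 and 9 at day 7 were reached by 7 and 8 splits, with up to 16. The 4 and 9 between the times were reached by 10 and 9, with up to 15.

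For 100 drawn splits of the 9 libraries into 3 groups, 5053 genes differing by the F test were reached by 1, the real one, and the highest other was 2486. In the other splits the 3 group names were given at random. The 980 genes higher and 1369 lower at both times were also reached by 1, with 3 and 10 as the highest others. Early rises, late rises, early falls and late falls were each reached by 3, so each of these shares of 100 is under 0.05. Other splits gave up to 1050, 855, 757 and 602 genes, several times the real 182, 282, 59 and 80. These larger counts came only from splits that kept the 3 sham libraries together. Of the other splits 4 kept the 3 sham libraries together, and for each of these 4 classes 2 of the 4 gave as many genes, while splits that parted sham gave at most 13. Where the sham libraries carried the name of an infarct group, differences between sham and infarct could count as early or late changes. The shares of these 4 classes therefore cannot decide on chance. They also say little on how the infarct libraries divide into day 1 and day 7. For the F test, which does not depend on the group names, 0 of the 4 gave as many, with 2486 as the highest count. For the genes higher or lower at both times the highest counts of the 4 were 0 and 0. These 2 classes depend on which libraries carry the name sham. With names given at random, the 0 and 0, and the 3 and 10 over all other splits, cannot decide on chance.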
